A study of Mus musculus with 24 samples.

How the data were processed

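The series holds 24 libraries of messenger RNA from mouse dendritic cells grown from bone marrow, in 8 groups of 3. Per the labels' protocols, cells came from C57BL/6JRj wild-type or Cas9-EGFP mice, and the genotype of each sample is not given in the sources used here. RNA was extracted with RNeasy kits, had an integrity number above 8, and was made into libraries with the TruSeq Stranded mRNA kit and sequenced on a NovaSeq6000, per the labels' protocols. The series describes the 3 libraries of a group as biological replicates. Titles name the libraries with GM-CSF alone DC105_1, DC105_2 and DC105_3, which share a culture number. Those with FLT3L as well are named DC91, DC94 and DC95, which do not. Whether the DC105 libraries come from separate animals is not given, so the spread within the 2 culture types may not be comparable. Reads were aligned to GRCm39 with STAR 2.7.3a and counted per gene with HTSeq 0.12.4, per the submitters' processing notes, which also name DESeq2 1.30.1. The strand setting of the counting and the annotation release are not given in the sources used here. For this reason genes that overlap another gene or its antisense partner are uncertain, as are members of families with near-identical copies (among those named: Trim43b, Apol7c, Hspa1b, Naip2, the MHC class I genes).

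The values used were the raw counts per gene that the authors deposited, with no normalisation, 55414 gene lines in each of 24 files in 1 gene order. Lines that name no gene stayed out of library sizes and tests. They took 10.98% to 16.4% of all counted reads per library: 2.71% to 6.76% had no feature, 6.01% to 12.1% a low alignment quality and 0.712% to 1.14% an ambiguous gene. The files give Ensembl identifiers. Symbols and biotypes were taken by identifier from an annotation of an earlier build (GENCODE M21, GRCm38), which named 52081 of the 55414 identifiers, and no coordinates are given.

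Groups were compared with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by TMM, low genes were removed by filterByExpr on the groups, and a robust quasi-likelihood model of group means without covariates was fitted. One model held the 15 GM libraries (16152 genes), another the 9 FL libraries (15961 genes) and another all 24 libraries (17262 genes), so that groups in a model shared an estimate of the spread. The biological coefficient of variation was 0.146, 0.390 and 0.272 in these models. Every adjusted p for a gene is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. The comparisons were each of 3 doses against DMSO, the slope over 0.1, 0.5 and 1 µM per 10-fold dose, and DMSO against t0 in GM cultures. In FL cultures they were 0.05 µM against DMSO and DMSO against t0. Across culture types they were FL against GM at t0, and the FL response at 0.05 µM minus the GM response at 0.1 µM. Genes called at an unadjusted p under 0.05 numbered 7691, 9421 and 9617 at 0.1, 0.5 and 1 µM, 5212 for the slope, 8614 for DMSO against t0 in GM cultures, 2790 for 0.05 µM and 4744 for DMSO against t0 in FL cultures, 8327 for FL against GM and 2277 for the difference of responses. Folds and levels are given in log2 and in CPM (gene counts scaled to a fixed library total), which were computed here from the deposited counts.

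Gene lists (20 pathway and 9 marker lists, 693 symbols, of which 1 had no identifier) were fixed from general knowledge of dendritic cells, IAP antagonists and bone marrow cultures. They were tested with camera in edgeR with limma 3.58.1 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Counts of members called are given over all genes tested and, where different, adjusted over the list alone. Where the text names an estimated correlation, camera estimated the correlation from the residuals of that list. Lists share genes, and macrophages and dendritic cells express many of the same ones, so a marker list describes levels in bulk RNA and does not count cells.

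Genes were named by rule. In each comparison these were the 8 largest rises and the 8 largest falls (5 each for the slope and the difference of responses) among called, protein-coding genes with a mean of at least 10 CPM in a group and the same direction in all 3 same-numbered pairs, or with groups that did not overlap for FL against GM, which chance gives in 10% of genes. GM doses were picked at 1 µM and given at the others. Named too were fixed panels (IAP, NF-kB, co-stimulation and MHC class I genes for AZD5582, cDC1 and macrophage genes for FL against GM), and up to 4 members of a list with the smallest p and up to 2 that went the other way. The text gives a selection of these, and some genes that the rule names are not reported here. The tests of the group comparisons and lists, the samples, gene lists, naming rule and all alternatives but those named at the end were fixed before the data were examined. The splits of the libraries and the tests of explanations, except the bound of the first slope test, were chosen after the results were seen.

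Per-library depth was 27.01 to 85.8 M gene counts (M for 10 to the power of 6). A fold against a group with 0 counts used a floor of 3 counts over the group, and ratios with 1 to 3 counts carry a 95% counting interval. These intervals and floors cover counting error only, since reads carry no molecular identifiers. Principal components used log2(CPM + 1). No pair of libraries was a duplicate by the spread of their counts, among genes with at least 20 counts.

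Whether same-numbered libraries deviate together was checked over 12541 genes with a mean of at least 1 CPM, by the correlation of deviations from the group means. All 3 pairs were over 0.1 for 1 µM against DMSO in GM cultures (0.105 to 0.227), 0.05 µM against DMSO in FL cultures (0.259 to 0.845) and DMSO against t0 in FL cultures (0.115 to 0.389), where FL culture numbers are also the culture names in the labels. In these 3 comparisons the model with the number as a block is given beside the main one where a call changed. For 0.1 and 0.5 µM against DMSO (0.033 to 0.181 and 0.073 to 0.163) and DMSO against t0 in GM cultures (0.071 to 0.103) the numbers did not pass this check. Titles carry the same numbers in every GM group, so missing this bound does not show that the libraries are unpaired. Between doses they passed for 0.1 with 0.5 µM (0.229 to 0.534) and 0.1 with 1 µM (0.166 to 0.465) and not for 0.5 with 1 µM (0.051 to 0.54), so the slope was not taken as paired.

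Comparisons that share the GM DMSO libraries were set beside 10 simulated draws of unchanged groups. Log2 changes at 0.1 and 0.5 µM had r = 0.885 and a covariance of 1.19 (simulated 0.484 and 0.053), and those at 0.5 and 1 µM r = 0.931 and 1.66 (simulated 0.483 and 0.0529). The simulated covariances argue against the spread of the shared controls as the source of most of the observed covariance. Controls of 3 libraries could not be divided, so a shift common to them stays open.

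The steps were tested on simulated counts with 200 changed genes. These draws held no shared culture effect and far fewer changed genes than the GM calls, so their rates may not carry over. With edgeR, 66% of 2-fold and 86% of 4-fold changes were recovered for 1 µM in GM cultures, with 5% of the calls false; 59% and 84% for the slope (4.7%); 4% and 50% for 0.05 µM in FL cultures (3.6%); 33% and 67% for FL against GM (4.8%); and 18% and 49% for the difference of responses (1.5%). DESeq2 1.42.0, used as an alternative, had 9%, 14.3%, 33.6%, 20.4% and 17% of its calls false in the same simulations. For the simulated changed lists camera gave p of at most 3.03e-30 and for random lists 0.327 to 0.934. Other alternatives were size factors by median of ratios (RLE), no filter on low counts, an adjusted p of 0.01, a model of the compared groups only or of all 24 libraries, the number as a block, fry in place of camera, DMSO in place of t0 libraries for FL against GM, and leaving out each library in turn. Alternatives added after seeing the data left out culture 91, with and without the block. They also repeated the list tests without single libraries, and with the block and an estimated correlation together.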

Results

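Messenger RNA was sequenced from mouse dendritic cells (DCs), the antigen-presenting cells that prime T cells, grown from bone marrow in 2 ways. In the first, cells received 20 ng/ml of the cytokine GM-CSF and were taken at day 8 (GM cultures, named monocyte-derived DCs in the series). In the second, cells received 20 ng/ml GM-CSF with 200 ng/ml FLT3L, a growth factor of DC precursors, and were taken at day 16 (FL cultures, named type 1 conventional DCs, or cDC1, in the series). Cells were collected at the start (t0) or after 24 h with AZD5582 or its solvent DMSO. AZD5582 is an antagonist of the inhibitor of apoptosis proteins (IAPs), of the class called SMAC mimetics, whose members lead to loss of cIAP1 and cIAP2 and release non-canonical NF-kB signalling. The series' title places the compound in a screen for molecules by which DCs drive T cell proliferation after cross-presentation. The GM cultures comprised t0, DMSO and AZD5582 at 0.1, 0.5 and 1 µM, and the FL cultures t0, DMSO and AZD5582 at 0.05 µM, with 3 libraries in each of the 8 groups. In M (10 to the power of 6) counts on genes, the 24 libraries held between 27.01 and 85.8, with a median of 51.7. Group means were 57.4 M for GM t0, 67.7 for GM DMSO, 48.4, 63.7 and 50.02 for GM cultures with 0.1, 0.5 and 1 µM, 52.4 for FL t0, 32.1 for FL DMSO and 58.8 for FL cultures with 0.05 µM. Between 18178 and 20534 genes were detected per library. Genes were counted by Ensembl identifier, for example ENSMUSG00000017652 for Cd40 and ENSMUSG00000027314 for Dll4.

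In GM cultures, the first principal component held 80.6% of the variance and separated t0 from DMSO libraries, and both from AZD5582 libraries. It ran from t0 (-100.55 to -99.17) and DMSO (-42.44 to -29.95) through 0.1 µM (22.51 to 33.06) to 0.5 µM (49.29 to 55.71) and 1 µM (54.21 to 59.01). In FL cultures it held 69.2%, and cultures of one group lay far apart after 24 h but not at t0. The DMSO library of culture 91 lay at 59.93, those of cultures 94 and 95 at -28.24 and -16.52, and the t0 libraries between -65.27 and -60.78. The AZD5582 libraries of cultures 91, 94 and 95 lay at 93.88, 21.75 and 56.04. One GM library at 1 µM (replicate 1) had 8.04% of its counts on mitochondrial genes against 3.96% and 4.27% in the other libraries of its group.

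**Figure D1:**
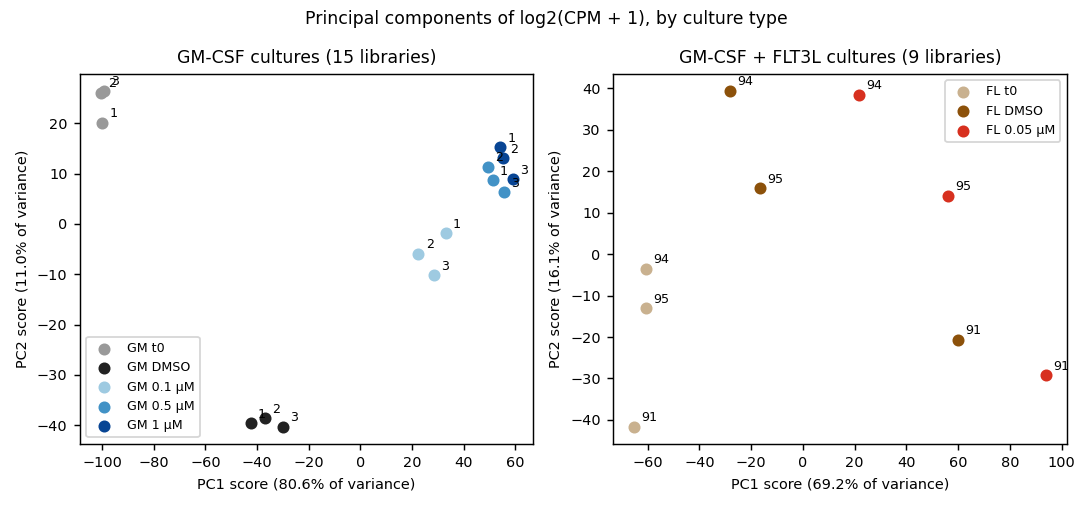
Scores of each library on the first and second principal components of log2 CPM, in GM cultures (left) and FL cultures (right). Points are libraries coloured by group; in GM cultures PC1 runs from t0 through DMSO and 0.1 µM to 0.5 and 1 µM, whose ranges overlap, while the FL DMSO library of culture 91 stands at 59.93 and the other FL DMSO libraries below 0.

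The culture types were compared at t0, where FLT3L, the day of culture and the cultures themselves differ together. Xcr1, the chemokine receptor of cDC1, stood at 212 ± 150 CPM in FL cultures and 0.139 ± 0.0307 in GM cultures (mean ± SD, n = 3 each), a log2 difference of 10.56 ± 0.68 (SE). Cadm1 (7.31 ± 0.41) and Clec9a (7.12 ± 0.47), a surface molecule and a dead-cell receptor of cDC1, were also higher in FL cultures. Lyz2, the myeloid lysozyme, stood at 18570 ± 2670 CPM in GM cultures and 591 ± 96.9 in FL cultures (-4.97 ± 0.27). Of genes outside these panels, the folate hydrolase relative Naalad2 had 2116 counts in FL cultures and none in GM cultures, at least 735-fold higher against a floor of 3 counts over the group. Arginase gene Arg1 (-11.14 ± 1.12) and the scavenger receptor gene Marco (-7.59 ± 0.72) were lower. The cDC1 transcription factors Batf3 (1.81 ± 0.12) and Irf8 (3.17 ± 0.36), the integrin gene Itgae (3.74 ± 0.73) and Flt3, the FLT3L receptor (5.59 ± 0.43), were higher in FL cultures. The macrophage growth factor receptor Csf1r (-2.60 ± 0.33), Adgre1 (-2.44 ± 0.48), the lipopolysaccharide co-receptor Cd14 (-3.06 ± 0.35) and the mannose receptor Mrc1 (-5.35 ± 0.50) were lower. Of 17262 genes tested, 7059 passed an adjusted p of 0.05, 4033 higher and 3026 lower in FL cultures.

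**Figure D2:**
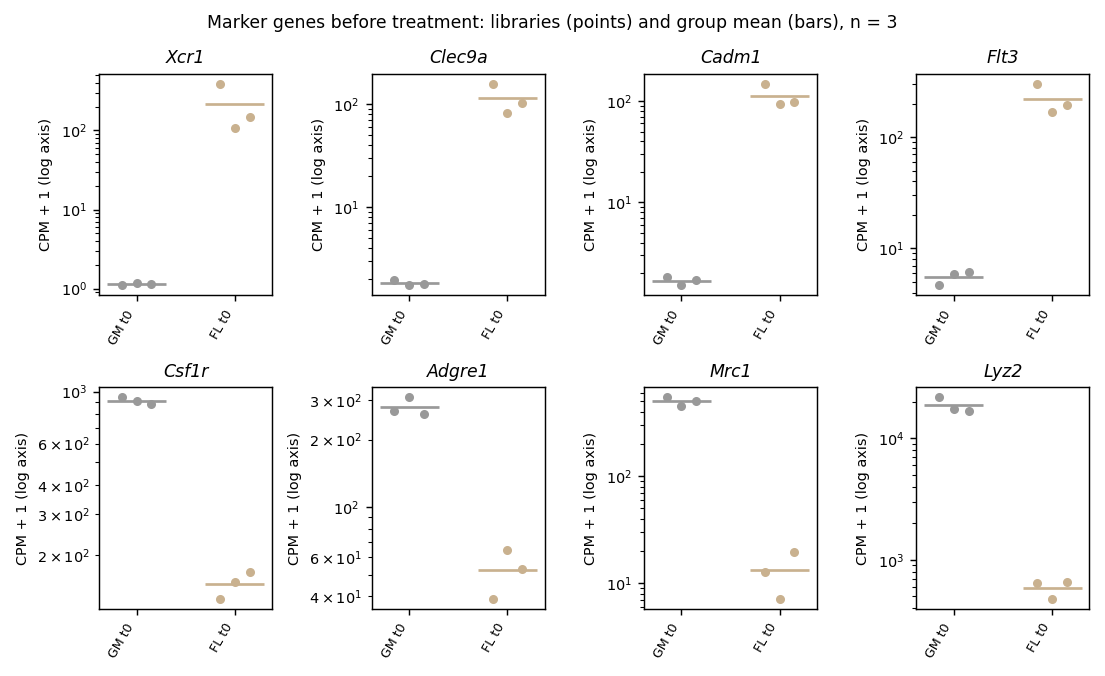
CPM + 1 on a log axis of 4 DC genes (Xcr1, Clec9a, Cadm1, Flt3) and 4 monocyte or macrophage genes (Csf1r, Adgre1, Mrc1, Lyz2) at t0. Points are libraries and bars are means of 3; the first 4 genes are higher in FL cultures and the last 4 in GM cultures.

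Among marker lists at t0, 20 of 24 cDC1 genes were higher in FL cultures and none lower (21 adjusted over the list alone; camera adjusted p = 3.556e-15, and adjusted p = 0.02501 with an estimated correlation). Of 29 monocyte and macrophage genes, 28 were lower, among them Mertk, a receptor for dying cells (-3.81 ± 0.19), and the lipoprotein gene Apoe (-4.57 ± 0.24). The list's adjusted p was 6.339e-35, and adjusted p = 0.003435 with an estimated correlation. Lysosome and phagocytosis genes were lower for 31 of 33, with the cathepsin genes Ctsd (-3.80 ± 0.28) and Ctsl (-3.27 ± 0.19; adjusted p = 1.723e-29, and adjusted p = 0.000339 with an estimated correlation). Genes of lipid export and the nuclear receptors LXR and PPARg were lower for 17 of 19, for example lipoprotein lipase Lpl (-4.27 ± 0.35; adjusted p = 1.674e-15, and adjusted p = 0.003435 with an estimated correlation). NF-kB genes (19 higher, 1 lower of 24; 20 and 1 over the list alone) included Traf1 (2.87 ± 0.33) and Relb (2.13 ± 0.34), and DC maturation genes (31 and 2 of 38; 31 and 3 over the list alone) included Cacnb3 (3.29 ± 0.28). Their adjusted p of 0.0003934 and 1.118e-14 were lost at adjusted p = 0.7453 and adjusted p = 0.2404 with an estimated correlation. Glycolysis and hypoxia genes (2 and 18 of 27) such as the enolase Eno1 (-1.62 ± 0.19), NRF2 targets (3 and 12 of 22) such as haem oxygenase Hmox1 (-2.69 ± 0.27) passed with the preset correlation. So did cytokine genes (5 and 12 of 29) such as Il1rn (-3.71 ± 0.26) and stem cell genes (8 and 0 of 13) such as Sox4 (2.31 ± 0.24). Their adjusted p of 4.012e-06, 0.001418, 0.006654 and 0.02839 rose to adjusted p = 0.2404, 0.3086, 0.2299 and 0.3086 with an estimated correlation. Of neutrophil and mast cell genes, 16 of 22 and 13 of 20 were higher in FL cultures, for example the granule protease Ctsg (5.54 ± 1.12) and the mast cell protease Cpa3 (4.06 ± 0.72), while the lists' adjusted p were 0.07403 and 0.115. Cell cycle genes did not pass (0 of 39 called; median log2 difference -0.371, adjusted p = 0.1546).

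In GM cultures, maturation and NF-kB genes were higher and cell cycle genes lower after 24 h in DMSO than at t0. Time in culture and the solvent differ together here. Of 38 maturation genes, 32 rose and 2 fell (33 and 2 adjusted over the list alone; adjusted p = 4.057e-49, and adjusted p = 0.00134 with an estimated correlation). The actin-bundling gene Fscn1 went from 175 ± 13.5 to 2781 ± 408 CPM (log2 3.98 ± 0.14, n = 3 each) and Serpinb6b rose by 4.54 ± 0.14, while the chemokine gene Ccl17 fell (-2.73 ± 0.78). Of 24 NF-kB genes, 22 rose (adjusted p = 3.954e-21, and adjusted p = 0.0009544 with an estimated correlation), with Relb, a subunit of the non-canonical pathway, at 3.05 ± 0.12 and Nfkb2, its partner, at 2.31 ± 0.12. The IAP genes Birc2 (2.23 ± 0.13) and Birc3 (2.06 ± 0.09) rose. All 39 cell cycle genes fell, for example the mitotic kinase gene Aurka (-3.03 ± 0.17; adjusted p = 1.628e-44, and adjusted p = 0.03199 with an estimated correlation). Of single genes, Apol7c rose from 11 ± 2.09 to 2365 ± 453 CPM (7.74 ± 0.21), with relatives in its family that may share reads, and Id3, a transcription regulator, rose by 6.67 ± 0.29. Scube3 had 1 count at t0 and 4349 in DMSO, a ratio of 4160 (95% counting interval 746 to 164000). Car4, a carbonic anhydrase (-5.84 ± 0.56), Cd300e (-5.48 ± 0.35), Itgae (-5.20 ± 0.42) and Plet1 (-4.66 ± 0.65) fell, and Il12b, a subunit of IL-12, rose (6.03 ± 0.32).

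A further 4 lists passed in this comparison with the preset correlation and not with an estimated one. The first was MHC class I (15 up, 0 down of 23; 16 over the list alone; 0.0009303, and adjusted p = 0.5825 with an estimated correlation). Another was cholesterol synthesis (2 and 17 of 22; 5.279e-05 and adjusted p = 0.4773). The others were NRF2 targets (15 and 0 of 22; 16 and 1 over the list alone; 0.006515 and adjusted p = 0.6569) and the type II interferon response (12 and 2 of 23; 0.02369 and adjusted p = 0.6569). Members that moved were Irf1 (3.14 ± 0.11), a transcription factor of interferon responses, Srxn1 (1.09 ± 0.13), a reductase, and Fdps (-1.33 ± 0.14), an enzyme of isoprenoid synthesis. Monocyte and macrophage genes (18 up, 5 down of 29) had an adjusted p of 0.0638, with Apoe at 789.6 ± 172 CPM after 24 h and 88.3 ± 25.8 at t0 (3.15 ± 0.19). In all, 7678 of 16152 genes passed, 4398 up and 3280 down.

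Against DMSO, AZD5582 in GM cultures raised Dll4, a Notch ligand, from 0.301 ± 0.122 CPM to 34.6 ± 5.56, 66.3 ± 9.45 and 75.8 ± 13 CPM at 0.1, 0.5 and 1 µM (n = 3 each), log2 changes of 6.94 ± 0.30, 7.90 ± 0.31 and 8.11 ± 0.31. The cytokine gene Il6 rose by 3.45 ± 0.30, 4.70 ± 0.32 and 4.77 ± 0.32, and Ptgs2, the inducible cyclooxygenase, by 3.53 ± 0.44, 4.47 ± 0.45 and 4.42 ± 0.45. Trim43b (6.79, 7.54 and 7.50, SE 0.33 each) rose as well, and has near-identical copies with which it may share reads. Sp6, a transcription factor (3.92, 5.25 and 5.25), Gjb2, a gap junction protein (4.18, 4.76 and 4.78), and Neurl1a (4.35, 5.92 and 5.96) were the other large rises. Enpp2, which makes lysophosphatidic acid, rose by 5.31 ± 0.83 and 5.50 ± 0.83 at 0.5 and 1 µM. At 0.1 µM its 2.76 ± 0.84 (adjusted p = 0.0194) was not called without DMSO library 1 (0.078), DMSO library 3 (0.0547) or 0.1 µM library 1 (0.0724). Among the largest falls, the lactoferrin gene Ltf fell by 5.50 ± 0.35, 8.21 ± 0.43 and 8.61 ± 0.46. The granule gene Ngp changed by -4.71, -7.88 and -8.13 and S100a9 by -4.73, -7.29 and -6.86. Arg1 changed by -3.54, -6.88 and -7.70, Fcrls by -6.28, -6.75 and -6.99, and the lectin genes Asgr2 and Mgl2 by -7.31, -7.12 and -7.43 and by -5.78, -6.23 and -6.77. Cd300lg had 3313 counts in DMSO and 2 at 1 µM, a ratio of 1120 (95% counting interval 311 to 9290).

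Of 16152 genes tested in GM cultures, 6503 passed at 0.1 µM (3220 up, 3283 down), 8641 at 0.5 µM (4164 and 4477) and 8899 at 1 µM (4350 and 4549). Changes of at least 2-fold among them numbered 1149 up and 1352 down at 0.1 µM, 1602 and 2327 at 0.5 µM, and 1671 and 2499 at 1 µM. With all 24 libraries in one model, 3874 genes passed at 0.1 µM. Both 0.1 and 1 µM called 2937 genes up and 2981 down, where independent lists would share 867.2 and 924.6. The log2 changes at 0.1 and 1 µM correlated across genes at r = 0.861 (covariance 1.24). Unchanged groups simulated against simulated DMSO libraries that they shared gave r = 0.479 (covariance 0.053). They shared 0 calls, but with at most 2 calls in a simulated comparison this decides nothing. The covariances argue against the spread of the shared controls as the source of most of the observed covariance. A shift common to the DMSO libraries was not simulated and stays open.

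Co-stimulatory and maturation genes rose at every dose in GM cultures. Cd40, the receptor of CD40 ligand, went from 64.0 ± 12.6 CPM to 255.0 ± 23.5, 347.8 ± 14.0 and 374.3 ± 35.1 (log2 2.06 ± 0.13, 2.53 ± 0.14 and 2.66 ± 0.14). The CD28 ligand genes Cd80 (1.92, 2.60 and 2.62) and Cd86 (1.87, 2.39 and 2.42), the lymph node homing receptor gene Ccr7 (1.36, 1.74 and 2.00), Tnfsf4, the OX40 ligand (2.24, 3.12 and 3.19), and Cd200 (2.36, 2.94 and 2.93) rose too. Of 38 maturation genes, 30 rose at 0.1 µM with none falling, and 32 rose and 1 fell at 1 µM (31 and 0, and 32 and 1, adjusted over the list alone). Icosl, the ICOS ligand gene, fell (-0.96 ± 0.24). The list's adjusted p was 3.777e-21 at 1 µM, and adjusted p = 0.01099 with an estimated correlation. Of 24 NF-kB genes, 19 rose and 2 fell at 1 µM (5.543e-07, and adjusted p = 0.01364 with an estimated correlation). Nfkb2 rose by 1.04, 1.24 and 1.41 (SE 0.11 each), the inhibitor genes Nfkbia by 1.32, 1.68 and 1.78 and Tnfaip3 by 1.90 ± 0.15 at 1 µM. Relb rose by 0.56, 0.56 and 0.67, and Traf1 by 0.96, 1.01 and 1.13, while Tnip3 fell (-1.45 ± 0.11). Map3k14, which encodes the kinase NIK, stood at 0.03 ± 0.10 at 1 µM (adjusted p = 0.827).

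**Figure D3:**
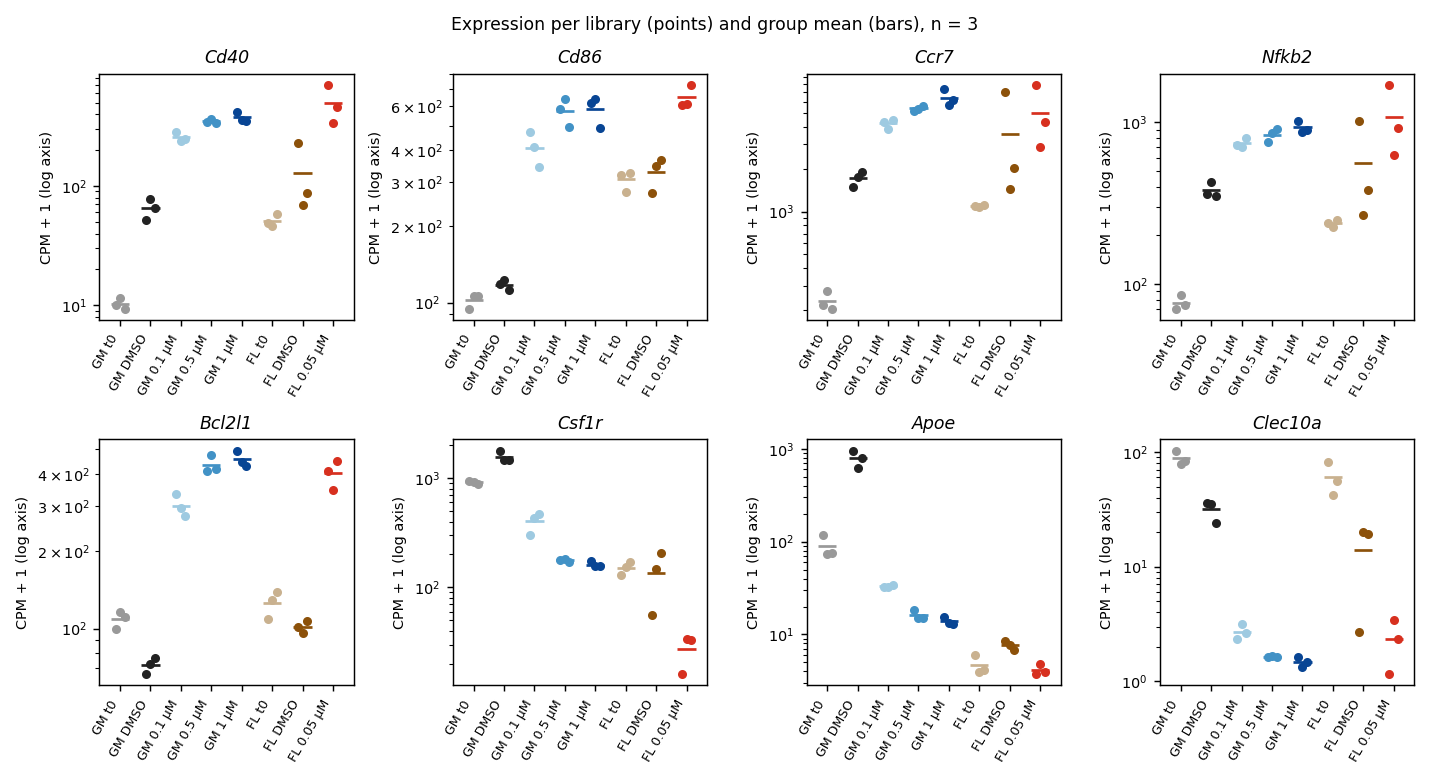
CPM + 1 on a log axis of Cd40, Cd86, Ccr7, Nfkb2, Bcl2l1, Csf1r, Apoe and Clec10a in the 8 groups. Points are libraries and bars are means of 3; in GM cultures the first 5 genes are higher and the last 3 lower with AZD5582 than with DMSO.

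Of the compound's target family, Birc2 rose by 0.66, 0.74 and 0.61 (SE 0.12 each), while Birc3 (0.22, 0.21 and 0.16; adjusted p = 0.0539, 0.0549 and 0.127) and Xiap (-0.02, 0.31 and 0.18, SE 0.14 each) did not pass. These depended on single libraries or on the method. Birc3 passed at 1 µM without 1 µM library 1 (0.243, adjusted p = 0.0139), and at 0.1 and 0.5 µM with median-of-ratios scaling (0.232 and 0.236), with DESeq2 and with the compared groups only. Without DMSO library 3, Xiap passed at 0.5 µM (0.519, adjusted p = 0.0016) and 1 µM (0.386, adjusted p = 0.012), and at 0.5 µM it also passed with DESeq2 (0.336) and with no filter (0.277). The IAP family list, which also holds its antagonists, had 2 members up and 7 down of 13 at 1 µM (adjusted p = 0.1333). Htra2, a mitochondrial protease that binds IAPs, rose (1.26 ± 0.08), and survivin gene Birc5, expressed in dividing cells, fell (-2.37 ± 0.24), as did Naip2 (-1.42 ± 0.13), one of several near-identical copies. Cell death genes went both ways (16 up, 13 down of 38; adjusted p = 0.3393; median 0.005, mean -0.021, test upward). Bcl2l1, which encodes the survival protein BCL-XL, rose from 71.1 ± 5.34 to 456.7 ± 32.8 CPM at 1 µM (2.15 ± 0.11, 2.7 ± 0.11 and 2.79 ± 0.11), and the caspase-8 inhibitor gene Cflar rose (1.06 ± 0.09). The TNF receptor gene Tnfrsf1a (-1.37 ± 0.11) and Tnfsf10, which encodes TRAIL (-3.41 ± 0.43), fell. TNF superfamily genes were 13 up and 14 down of 29 (adjusted p = 0.9742). Tnf itself fell at 0.5 µM (-0.71 ± 0.17) and 1 µM (-0.95 ± 0.17). Its -0.44 ± 0.17 at 0.1 µM (adjusted p = 0.0452) was not called without DMSO library 1 or 2 (0.175 and 0.196) or without 0.1 µM library 1, 2 or 3 (0.0635, 0.0784 and 0.146).

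Antigen presentation genes divided by class at 1 µM. Of 23 MHC class I genes, 16 rose and 2 fell (17 and 2 over the list alone; adjusted p = 0.0001805, and adjusted p = 0.3016 with an estimated correlation). The proteasome activator genes Psme1 (1.3 ± 0.12) and Psme2 (1.62 ± 0.12), Tapbpl, a peptide editor (1.45 ± 0.13), H2-K1 (0.42, 0.51 and 0.50), B2m (0.58, 0.61 and 0.89) and the peptide transporter gene Tap1 (0.50, 0.44 and 0.43) rose. Of 16 MHC class II genes, 2 rose and 12 fell (adjusted p = 0.00472, and adjusted p = 0.3016 with an estimated correlation). Ctss, a cathepsin that trims the invariant chain, went from 4020 ± 263 to 1302 ± 77.6 CPM (-1.52 ± 0.10), H2-DMb1 fell (-1.62 ± 0.13), and Ifi30, a lysosomal reductase, rose (0.77 ± 0.12). Cross-presentation genes were 9 up and 18 down of 35 (0.01421, and adjusted p = 0.09403 with an estimated correlation). Wdfy4, needed for cross-presentation by cDC1 (-3.26 ± 0.15), the receptor genes Axl (-2.42 ± 0.11) and Mrc1 (-2.89 ± 0.14) and the oxidase subunit gene Cybb (-2.27 ± 0.13) fell, and another subunit of that oxidase, Ncf1, rose (1.33 ± 0.10).

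Genes of the type I interferon response were 7 up and 29 down of 40 at 1 µM (8.262e-05, and adjusted p = 0.4983 with an estimated correlation). There were falls in the adhesion receptor gene Siglec1 (-3.05 ± 0.25), Ifi204 (-2.88 ± 0.17) and Rigi, an RNA sensor (-1.55 ± 0.13). The type II response had 6 up and 14 down of 23 (7 and 14 over the list alone; adjusted p = 0.4189), with Irf1 (1.61 ± 0.10) and the checkpoint ligand gene Cd274 (1.08 ± 0.10) up and the chemokine gene Cxcl10 down (-2.05 ± 0.23). Inflammatory cytokines and chemokines were 10 up and 14 down of 30 (11 and 14 over the list alone; adjusted p = 0.4189; median -0.495, mean 0.27, test upward). Besides Il6, Csf1 (2.21 ± 0.12), Cxcl16 (1.16 ± 0.09) and the IL-1 receptor antagonist gene Il1rn (1.28 ± 0.12) rose, Il18 fell (-2.53 ± 0.24), and Il12b rose by 1.70, 2.25 and 2.26.

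Lysosome genes fell for 24 of 32 at 1 µM and rose for 3 (adjusted p = 1.392e-13, and adjusted p = 0.03184 with an estimated correlation). Stab1, a scavenger receptor (-4.05 ± 0.16), Ctsa (-1.91 ± 0.09) and the integrin gene Itgam (-3.30 ± 0.17) fell, and Mfge8, a bridging protein for dying cells, rose (1.07 ± 0.19). LXR and PPARg genes fell for 13 of 19, with 1 up (1.076e-05, and adjusted p = 0.03184 with an estimated correlation). Apoe went from 789.6 ± 172 to 12.9 ± 1.46 CPM (-5.82 ± 0.22), Pparg (-2.13 ± 0.15) and the desaturase gene Scd1 (-2.29 ± 0.13) fell, and Nr1h3, which encodes LXR alpha, rose (1.38 ± 0.20). With same-numbered libraries paired, the adjusted p with an estimated correlation was 0.09031 for lysosome genes and 0.07554 for LXR and PPARg genes, while with the preset correlation it ranged over the alternatives from 2.362e-14 to 1.615e-13 and from 4.826e-06 to 1.638e-05. Glycolysis and hypoxia genes were 3 up and 21 down of 27 (4 and 21 over the list alone; 2.354e-05, and adjusted p = 0.389 with an estimated correlation). The hexokinase gene Hk2 (-2.46 ± 0.14) and Pfkl (-2.40 ± 0.19) fell, and Ndrg1 (2.02 ± 0.15) and Pfkfb3 (1.44 ± 0.14) rose. Of 22 cholesterol synthesis genes, 2 rose and 18 fell at 0.1 µM (2 and 19 over the list alone; 2.265e-06, and adjusted p = 0.2624 with an estimated correlation), and at 1 µM 4 rose and 8 fell (0.5195). The slope of this list over the doses had an adjusted p of 2.565e-10, and adjusted p = 0.07746 with an estimated correlation. Insig1, a sterol-regulated brake on the pathway, fell (-1.69, -1.44 and -1.18), and Idi1, an isomerase of the pathway, rose (1.18, 1.80 and 1.49).

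Cell cycle genes fell at 0.5 and 1 µM. At 0.1 µM, 3 rose and 3 fell of 39 (1 and 3 over the list alone; median -0.049, adjusted p = 0.8462). At 0.5 µM 1 rose and 35 fell (1.419e-07, and adjusted p = 0.3716 with an estimated correlation), and at 1 µM 1 rose and 35 fell (1.186e-08, and adjusted p = 0.3538 with an estimated correlation). The mitotic genes Plk1 (-3.00 ± 0.22) and Ccnb2 (-3.22 ± 0.20) and the transcription factor gene E2f1 (-2.04 ± 0.12) fell, and thymidylate synthase gene Tyms rose (1.92 ± 0.23). Stress lists did not pass at 1 µM. This held for ER stress (11 up, 13 down of 28; 12 and 14 over the list alone; adjusted p = 0.8927) and p53 targets (11 and 2 of 23; 0.2027). It held for NRF2 targets (9 and 8 of 22; 0.8927; median 0.219, mean -0.002, test downward) and immediate early and heat shock genes (10 and 10 of 25; 10 and 11 over the list alone; 0.8482; median 0.13, mean -0.018, test upward). Members that passed included the p53 target Cdkn1a, which arrests the cell cycle (1.31 ± 0.11), Psat1, a serine synthesis enzyme (1.47 ± 0.10), and Herpud1, of the ER stress list (-1.17 ± 0.10). Others were the quinone reductase gene Nqo1 (1.57 ± 0.27), the glutathione transferase gene Mgst1 (-2.04 ± 0.16), the early response genes Nr4a2 (2.92 ± 0.25) and Egr1 (-2.95, -4.33 and -4.39), and the heat shock gene Hspa1b (3.96 ± 0.23), a near-identical copy of Hspa1a.

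Markers of monocytes, macrophages, neutrophils and type 2 conventional DCs (cDC2) fell together with the lists above. Of 29 monocyte and macrophage genes, 25 fell at 0.1 µM and 28 at 1 µM, with none rising (0 and 29 over the list alone at 1 µM; adjusted p = 7.177e-28, and adjusted p = 0.01099 with an estimated correlation). Csf1r went from 1575 ± 181 to 160.9 ± 9.29 CPM (-1.91, -3.07 and -3.18). Of 22 neutrophil genes 20 fell at 1 µM (1.048e-12, and adjusted p = 0.01752 with an estimated correlation), with Lcn2 (-6.04 ± 0.26), Csf3r (-4.68 ± 0.22) and Hp (-4.31 ± 0.20). Of 19 cDC2 genes 14 fell and 3 rose (2.27e-10, and adjusted p = 0.01099 with an estimated correlation). The lectin genes Clec10a (-4.13, -5.50 and -5.90) and Clec12a (-3.66 ± 0.15) fell, and Esam rose (1.78 ± 0.24). The cDC1 list had 5 up and 12 down of 23 (0.1741), with Irf8 (1.18, 1.5 and 1.71) and Zbtb46, a transcription factor of conventional DCs (1.63 ± 0.12), up and Naaa (-2.86 ± 0.17) and Rab7b (-2.14 ± 0.13) down. Plasmacytoid DC genes were 7 up and 7 down of 18 (0.7174; median 0.052, mean -0.869, test upward), with the transcription factor genes Spib (1.51 ± 0.13) and Tcf4 (1.38 ± 0.11) up and Lair1 down (-2.05 ± 0.11). Mast cell, basophil and eosinophil genes were 7 up and 1 down of 19 (4 and 1 over the list alone; 0.504), with Prg2 up (1.08 ± 0.27) and Siglecf down (-3.64 ± 0.23). Lymphoid genes were 7 up and 1 down of 12 (0.1646), with the B cell gene Cd79a (1.93 ± 0.27) up at a level of 5.55 ± 0.873 CPM. Erythroid and megakaryocyte genes were 2 up and 1 down of 6 (0.9909; median 0.178, mean 0.628, test downward), with Pf4 down (-2.37 ± 0.25). Stem cell genes were 3 up and 3 down of 12 (0.8482), with Flt3 up (0.86, 1.07 and 1.01).

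**Figure D4:**
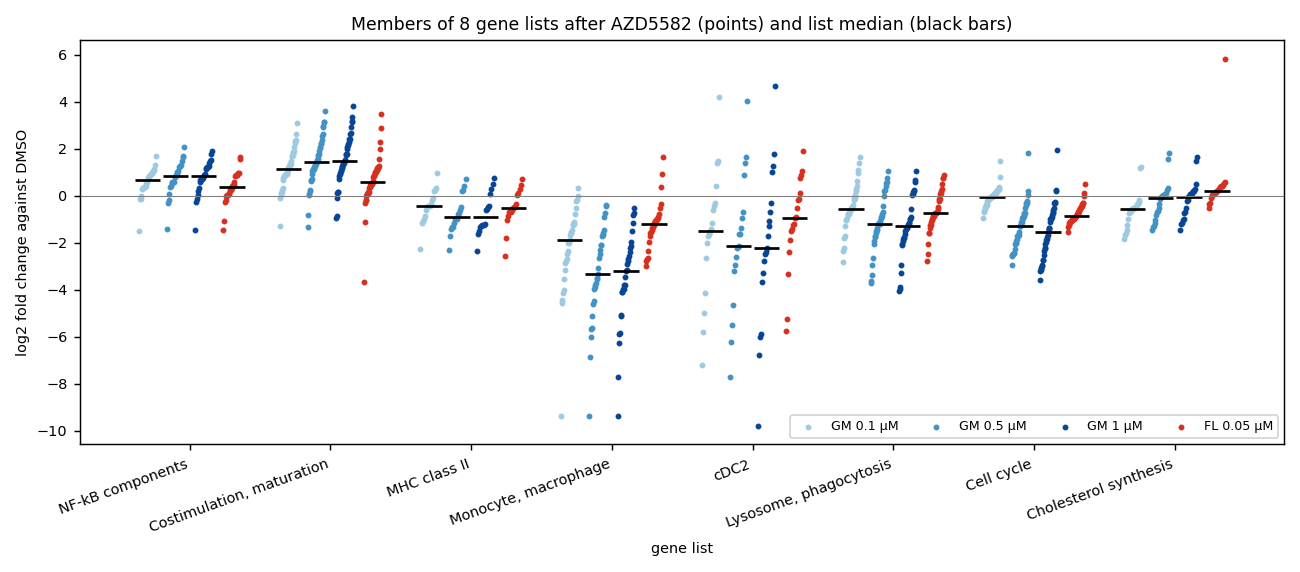
Log2 fold change against DMSO of each member of 8 gene lists in GM cultures at 0.1, 0.5 and 1 µM and in FL cultures at 0.05 µM. Points are genes and black bars are medians; the monocyte and macrophage list has a median of -3.22 at 1 µM in GM cultures.

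From 0.1 to 1 µM, the change per 10-fold dose was tested as a slope. Ccr2, a monocyte chemokine receptor, fell by 3.29 ± 0.27 per 10-fold dose, from 47.2 ± 17.9 CPM at 0.1 µM to 5.32 ± 1.31 at 1 µM. The formyl peptide receptor gene Fpr1 (-2.94 ± 0.22), the acute phase gene Saa3 (-2.69 ± 0.27) and the mitotic genes Ccna2 (-3.18 ± 0.32) and Kif20a (-2.71 ± 0.23) fell. Enpp2 rose by 2.90 ± 0.71 (adjusted p = 0.0127) and was not called without 0.1 µM library 3 (0.063). Other rises were those of Neurl1a at 1.72 ± 0.36, Afap1l2, a signalling adaptor, at 1.48 ± 0.24, Sp6 at 1.43 ± 0.25, Il6 at 1.40 ± 0.27, Cd40 at 0.61 ± 0.13, Cd86 at 0.58 ± 0.13, Ccr7 at 0.62 ± 0.13 and Bcl2l1 at 0.67 ± 0.10. The slopes of Relb (0.09 ± 0.11), Traf1 (0.15 ± 0.12) and Birc2 (-0.02 ± 0.12) did not pass. Of the 16152 genes 3288 passed, 1206 up and 2082 down. The count was 2009 without 0.1 µM library 2, 2108 without 0.1 µM library 3, and 668 with all 24 libraries in one model.

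Along the slope, 35 of 39 cell cycle genes fell (1.058e-41, and adjusted p = 0.03533 with an estimated correlation), as did 28 of 32 lysosome genes (1.02e-31, and adjusted p = 0.007254 with an estimated correlation). So did 12 of 19 LXR and PPARg genes, among them the cholesterol exporter gene Abca1 (-1.43 ± 0.14; 1.327e-08, and adjusted p = 0.01739 with an estimated correlation). Monocyte and macrophage genes fell for 25 of 29, with Lyz2 at -1.36 ± 0.13 (8.034e-31, and adjusted p = 0.007254 with an estimated correlation), neutrophil genes for 12 of 22 (6.414e-10 and adjusted p = 0.03533) and cDC2 genes for 7 of 19 (8.491e-06 and adjusted p = 0.04159). The IAP family list fell for 6 of 13 with 1 up, and Birc5 at -2.42 ± 0.22 (0.004089, and adjusted p = 0.03726 with an estimated correlation). Cholesterol synthesis genes rose for 15 of 22 and fell for 1 (20 and 1 over the list alone; 2.565e-10, and adjusted p = 0.07746 with an estimated correlation). Sqle, an enzyme of the pathway (0.82 ± 0.10), and the sterol carrier gene Stard4 (0.74 ± 0.11) rose, and Dhcr7 fell (-0.77 ± 0.09). Type I interferon genes fell for 28 of 40, with Siglec1 at -2.35 ± 0.23. Maturation genes rose for 19 and fell for 1 of 38 (25 and 1 over the list alone), and NF-kB genes rose for 8 of 24 (10, with 1 down, over the list alone). Their adjusted p of 1.354e-13, 3.857e-08 and 0.0005146 became adjusted p = 0.1445, 0.08596 and 0.06155 with an estimated correlation. ER stress and NRF2 target genes (adjusted p = 0.2329 and 0.1049) passed without 1 µM library 1, the one with the high mitochondrial share (0.03976 and 0.0005554, with up to 0.2293 and 0.0709 over their alternatives).

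In FL cultures, 0.05 µM AZD5582 raised Dll4 from 0.797 ± 0.440 to 29.3 ± 13.3 CPM (log2 5.19 ± 0.59, adjusted p = 0.00783, n = 3 each) and Bcl2l1 from 100.5 ± 5.44 to 401.9 ± 51.5 CPM (2.00 ± 0.17, adjusted p = 0.00288). Cd86 rose (0.98 ± 0.18, adjusted p = 0.0338), as did Tnfsf9, the 4-1BB ligand (2.89 ± 0.26), Cd70, the CD27 ligand (3.48 ± 0.46), the chemokine genes Ccl22 (2.27 ± 0.30) and Cxcl1 (3.67 ± 0.26), Nfkbia (1.63 ± 0.25), and Gli1, a transcription factor of Hedgehog signalling (5.29 ± 0.86). Xcr1 fell from 16.6 ± 9.39 to 2.07 ± 0.600 CPM (-3.00 ± 0.60), as did Cadm1 (-1.60 ± 0.28), and the RNA sensor gene Tlr3 (-4.40 ± 0.90). Other genes of the cDC1 list, Irf8 and Gcsam, did not pass (adjusted p = 0.196 and 0.2). With cultures paired both were called upward (1.437 and 2.012, adjusted p = 0.0089 and 0.0033). The complement genes C1qa (-2.66 ± 0.31), C1qb (-2.68 ± 0.36) and C1qc (-3.00 ± 0.34) fell. So did Asgr2 (-5.89 ± 1.10) and Pmaip1, which encodes the death protein NOXA (-1.36 ± 0.24). Trim43b (5.95 ± 0.69) and Hspa1b (4.20 ± 0.33), which have near-identical copies, rose. Cd40 had a log2 change of 1.97 ± 0.46 (adjusted p = 0.0635), and with cultures paired 2.07 with an adjusted p of 0.0168. Without the DMSO library of culture 91 it was 2.74 (adjusted p = 0.00439). Cd80 (0.63 ± 0.22), Ccr7 (0.50 ± 0.58), Il12b (1.22 ± 1.18), Nfkb2 (0.95 ± 0.52), Birc2 (0.02 ± 0.31) and Birc3 (0.37 ± 0.32) did not pass. Without the DMSO library of culture 91, Ccr7 (1.568, adjusted p = 0.0387), Nfkb2 (1.793, adjusted p = 0.0277) and Birc3 (0.904, adjusted p = 0.0255) passed. That setting kept the AZD5582 library of culture 91, and with cultures paired Ccr7, Nfkb2 and Birc3 did not pass. Of the 52 named genes called here, 24, 39 and 9 were called without the AZD5582 library of culture 91, 94 or 95, 52, 25 and 5 without the DMSO library of culture 91, 94 or 95, and 50 with cultures paired.

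Of 15961 genes tested, 463 passed in FL cultures at 0.05 µM, 258 up and 205 down, and with cultures paired 1098 passed (589 up, 509 down). Leaving out the DMSO library of culture 91 gave 1983, that of culture 94 gave 133 and that of culture 95 gave 17. Leaving out the AZD5582 library of culture 91 gave 156 and that of culture 95 gave 32. The lists below passed with the preset correlation and none passed with an estimated correlation (adjusted p = 0.5222 to 0.6588). Maturation genes rose for 5 of 38 (9 over the list alone; 4.002e-10). Monocyte and macrophage genes fell for 5 of 26 with 1 up, Mertk at 1.66 ± 0.21 (12 and 1 over the list alone; 5.854e-10). The cDC1 genes fell for 4 of 24 (5 over the list alone; 0.001301, and 0.07927 with cultures paired, within 3.53e-09 to 0.07927 over the alternatives). Lysosome genes fell for 2 of 33 (12 down and 3 up over the list alone; 0.0004019), with Ctsl at -1.57 ± 0.24. The LXR and PPARg genes fell for 2 of 18 (7 over the list alone; 0.004035) and cDC2 genes for 2 of 19 (6 down and 2 up over the list alone; 0.01696). With 1 member or fewer called in each direction, MHC class I (1.756e-05) and NF-kB genes (0.009526) tested upward, and neutrophil (3.628e-06), cell cycle (0.0008226) and lymphoid genes (0.0411) downward. MHC class II genes (0.03111) were lost with cultures paired (0.07612, within 0.001957 to 0.07612). Type I interferon (0.005823), NRF2 (0.01286) and cytokine genes (2 of 26 up; 0.03111) were lost without the DMSO library of culture 91 (0.09075, 0.1343 and 0.1964). Over the alternatives they ranged from 0.009253 to 0.1772, 0.001345 to 0.2603 and 0.04 to 0.1964. Cholesterol genes passed without that library (0.01474, with 0.06992 when it was kept and 0.0786 the highest over the alternatives). The mean log2(CPM + 1) of neutrophil genes also differed between cultures, at 4.53, 6.91 and 5.85 in the DMSO libraries of cultures 91, 94 and 95 and 2.31, 5.85 and 3.41 in the AZD5582 libraries.

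FL cultures after 24 h in DMSO were compared with t0, a comparison in which time in culture and the solvent differ together. Xcr1 fell from 212 ± 150 to 16.6 ± 9.39 CPM (-3.67 ± 0.60, adjusted p = 0.0168, n = 3 each), and Cadm1 (-1.57 ± 0.28), Ciita, the regulator of MHC class II genes (-2.05 ± 0.39), and H2-Ab1 (-1.48 ± 0.32) fell, while Batf3 rose (1.11 ± 0.15). Id3 (3.35 ± 0.56), Il1b (3.93 ± 0.71), Ido1, a tryptophan-degrading enzyme (3.11 ± 0.45), Nfkbia (1.09 ± 0.25) and Birc2 (1.48 ± 0.32) rose. Birc3 stood at 1.19 ± 0.33 (adjusted p = 0.0519, 0.0265 with cultures paired, and 0.0359 without the DMSO library of culture 94). The cholesterol synthesis genes Lss (-2.16 ± 0.22), Insig1 (-1.76 ± 0.19) and Cyp51 (-1.19 ± 0.15), the desaturase gene Scd1 (-3.01 ± 0.27), the interferon-induced genes Oas3 (-2.01 ± 0.32) and Dhx58 (-1.76 ± 0.29), and the chaperone gene Hspa5 (-1.14 ± 0.18) fell. Of the 96 named genes called here, 3, 34 and 5 were called without the t0 library of culture 91, 94 or 95, 73, 83 and 70 without the DMSO library of culture 91, 94 or 95, and 96 with cultures paired. In all, 1619 genes passed (792 up, 827 down), and 3107 with cultures paired (1473 up, 1634 down). The count was 13 without the t0 library of culture 91 or of culture 95, 232 without that of culture 94, 790 without the DMSO library of culture 95 and 998 without that of culture 91.

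Lists in this comparison passed with the preset correlation and none with an estimated one. Maturation genes rose for 21 of 38 (31 over the list alone; 2.281e-14, and adjusted p = 0.4684 with an estimated correlation). Cholesterol genes fell for 12 of 23 (13 over the list alone; 1.218e-13 and adjusted p = 0.2859), and type I interferon genes fell for 15 of 40 (20 down and 1 up over the list alone; 3.869e-09 and adjusted p = 0.3814). The cholesterol list had adjusted p = 0.02718 with an estimated correlation when cultures were paired. Of cDC1 genes 8 fell and 1 rose of 24 (15 and 1 over the list alone; 7.389e-07 and adjusted p = 0.4684). Of MHC class II genes 5 of 16 fell (10 down and 1 up over the list alone; 0.001826 and adjusted p = 0.4753). Of ER stress genes 7 fell and 2 rose of 28 (10 and 5 over the list alone; 0.001399 and adjusted p = 0.222). NF-kB genes rose for 3 of 24 (12 over the list alone; 7.313e-06 and adjusted p = 0.6342), and cell cycle genes fell for 2 of 39 (9.626e-10 and adjusted p = 0.6148). Cytokine (0.04777), NRF2, neutrophil and mast cell lists (0.04279 each) tested upward with at most 4 members called. Glycolysis genes (5 down, 1 up of 27; 0.02958) were lost without the DMSO library of culture 91 (0.0513, within 0.008971 to 0.0513), and monocyte and macrophage genes (0 of 26 called; 0.07318) passed without it (0.0016, within 4.468e-05 to 0.07114). Type II interferon (9 up, 3 down of 21; 0.0477) and immediate early genes (1 up, 3 down of 25; 0.04279) were lost with cultures paired (0.07618 and 0.09546, the highest over the alternatives, with 0.001965 and 0.01235 the lowest).

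The response of FL cultures to 0.05 µM was set beside that of GM cultures to 0.1 µM. Dose and culture type differ in this comparison, and with the type the day of culture. Of the 457 genes called in FL cultures and tested in both, 223 were called up and 155 down in both, where independent lists would share 53.1 and 41.7. Another 1 and 2 were called in opposite directions. Called or not in GM cultures, 434 of the 457 had the same sign there. Log2 changes correlated across genes at r = 0.626, with no control libraries in common. Apoe fell in GM cultures from 789.6 ± 172 to 31.9 ± 1.17 CPM and stood at 6.73 ± 0.877 and 3.16 ± 0.527 CPM in FL cultures with DMSO and AZD5582, a difference of the log2 changes of 3.54 ± 0.31 (adjusted p = 6.215e-06). The fibronectin gene Fn1, at 1089 CPM with DMSO and 47.3 with AZD5582 in GM cultures and 31.1 and 40.8 in FL cultures, differed by 4.92 ± 0.60, and Traf4, a signalling adaptor (4.11 and 34.9, and 27.8 and 35.2 CPM), by -2.75 ± 0.28. Insig1 fell in GM cultures from 60.3 to 17.8 CPM and stood at 43.5 and 43.1 CPM in FL cultures. Of 23 cholesterol synthesis genes 8 differed upward and none downward (15 over the list alone; adjusted p = 6.154e-23, and adjusted p = 0.01932 with an estimated correlation). In all, 289 of 17262 genes differed, 167 upward and 122 downward. The count was 93, 126 and 111 without GM DMSO library 1, GM DMSO library 2 and GM 0.1 µM library 1, 140 and 180 without GM 0.1 µM library 2 and 3, and 591 without the FL DMSO library of culture 91. Of 100 drawn splits of the libraries, the real one included, 24 gave as many genes. The splits shuffle AZD5582 and DMSO libraries within a culture type, so this share does not measure chance for a difference of responses. Chance was thus not excluded for this count. Numbers pair the FL libraries and not the GM libraries here, and with the number as a block 738 genes differed. The 4 genes given here were called without each library in turn.

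**Figure D5:**
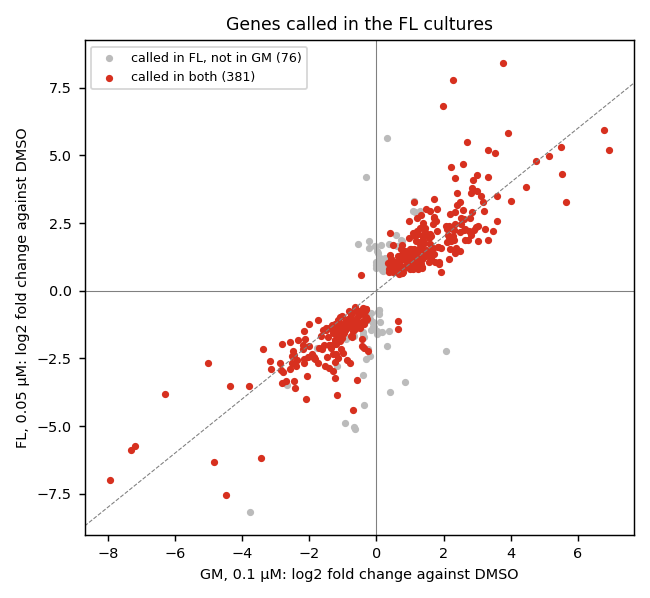
Log2 change with 0.05 µM AZD5582 in FL cultures (vertical axis) against that with 0.1 µM in GM cultures (horizontal axis) for the genes called in FL cultures and tested in both. Points are genes and the dashed line has slope 1; 223 genes were called up and 155 down in both.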

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

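The tests of cell mix, scaling and dose in GM cultures, the second slope test, the list tests without single libraries, the readings of counts without single libraries as explanations, and the splits of the libraries were chosen only after the result was seen.

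A difference between groups stood out in the response of FL cultures at 0.05 µM against that of GM cultures at 0.1 µM, for which 289 genes differed by a direct test. Among the called genes that met the level and direction limits of the naming rule, the largest positive differences of log2 changes were Fn1 4.92, Il18r1 4.31, Ltb4r1 4.15, Apoe 3.54 and F13a1 3.19. The most negative among them were Ppbp -3.78, Pdpn -3.03, Traf4 -2.75, Cyp1b1 -2.72 and Dnah2 -2.64. Members of the cholesterol synthesis list that differed included Insig1 (1.75), Stard4 (1.71), Msmo1 (1.53) and Sc5d (1.43). Of the 32 named genes called here, 20, 24 and 26 were called without the FL AZD5582 library of culture 91, 94 or 95, and 30, 26 and 22 without the FL DMSO library of culture 91, 94 or 95. Without GM 0.1 µM library 1, 2 or 3 there were 14, 20 and 22, and without GM DMSO library 1, 2 or 3 there were 13, 13 and 28. Il18r1 was not called without the FL AZD5582 library of culture 94, GM 0.1 µM library 1, 2 or 3, or GM DMSO library 1 or 2 (adjusted p 0.0516 to 0.0751). F13a1 was not called without the FL AZD5582 library of culture 94, GM 0.1 µM library 1, or GM DMSO library 1 or 2 (0.0531 to 0.073). Cyp1b1 was not called without the FL AZD5582 library of culture 91 or 95, the FL DMSO library of culture 94, GM 0.1 µM library 1 or 2, or GM DMSO library 1 or 2 (0.052 to 0.0852).

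Lists that differed, with adjusted p from camera, were cholesterol synthesis (6.154e-23), glycolysis and hypoxia (7.046e-07), cell cycle (7.956e-05), NRF2 targets (0.0002223), monocyte and macrophage markers (0.0002223), DC maturation (0.002054), cDC1 markers (0.00895) and lymphoid markers (0.00895). With an estimated correlation cholesterol synthesis passed (adjusted p = 0.01932) and the other 7 did not. Without the FL DMSO library of culture 91, the maturation list turned the other way (0.5565, within 0.002487 to 0.5565 over the alternatives), and the monocyte list did not pass (0.1098, within 0.0001011 to 0.1098), while the cholesterol list had 2.883e-24 (4.127e-27 to 4.665e-22 over the alternatives). Dose and culture type differ together in this comparison, and the types also differ in the day of culture and in culture names. None of these can be named as the source.

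For the difference of responses, 24 of 100 drawn splits of the libraries, out of 200 in all and the real one included, gave as many genes as the real 289. The highest other gave 4037. These splits shuffle AZD5582 and DMSO libraries within a culture type, which removes the responses and does not make them equal. Their share therefore does not measure chance for a difference of responses, and chance was not excluded. The split with 4037 is among 44 of the 100 that leave both libraries of culture 91 in one group, of which 13 gave as many as 289. Of the 40 drawn splits that part every FL culture 10 gave as many, with 1942 the highest other, but 10 of these 40 keep the real FL groups and with them the FL response. Of the 30 others 3 gave as many. With the number as a block 738 genes differed. For the dose slope, 1 of 100 drawn splits of 840, the real one, gave as many as 3288 genes and the highest other gave 2068, so chance was excluded for splits drawn without regard to the library numbers. With the number as a block the slope had 3708 genes. The comparisons of 3 libraries against 3 have 10 splits, too few for a share under 0.05. Their real values and highest others were 6503 and 0 at 0.1 µM, 8641 and 0 at 0.5 µM, 8899 and 19 at 1 µM, 7678 and 0 for DMSO against t0 in GM cultures, 1619 and 0 for DMSO against t0 in FL cultures, and 7059 and 0 for FL against GM, each with 1 split as large. For 0.05 µM in FL cultures they were 463 and 3966, with 2 splits as large. The split with 3966 sets both libraries of culture 91 with the AZD5582 library of culture 95 against the rest, a structure of the cultures. Among the 4 splits that part all pairs of a culture, the highest other than the real one gave 0.

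In GM cultures at 1 µM, monocyte and macrophage markers fell while maturation genes rose. Library scaling is argued against, since a factor per library moves all genes alike. The median of the monocyte list lay below that of the maturation list (difference -4.69, 29 and 38 members, SE of the difference of means 0.424). A lower share of monocytes and macrophages alone, with the other cells unchanged, would raise the markers of the other cell types alike. The median of the neutrophil list (-4.339, 22 members) lay below that of the mast cell, basophil and eosinophil list (0.878, 19 members). Their difference was -5.22 (SE of the difference of means 0.552). This cannot decide the question, because monocytes also express some genes of the neutrophil list, so that explanation stays open. Both SEs take genes as independent. A change that grows with the dose of AZD5582 stays open. Along the slope 25 of 29 members fell, but that count had been seen when the test was set and lends it no support. A fall in the shares of several cell types together and a change within cells were not tested against each other and both stay open, since bulk RNA does not count cells.

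In FL cultures few genes were called at 0.05 µM. The spread between culture 91 and the other cultures is a candidate source. Without its DMSO library 1983 genes were called, but that left its AZD5582 library without a partner. With cultures paired 1098 were called, and 2283 without any library of culture 91 (3958 with pairing too). These counts do not tell its DMSO library apart from the culture as a whole. A smaller effect than in GM cultures cannot be told apart from an equal one, because the slope of FL on GM log2 changes over 5734 genes (0.406, 0.468 and 0.663 in cultures 91, 94 and 95, mean 0.51) was set beside a bound of 0.8 that GM cultures themselves missed in 2 of 3 cases (0.823, 0.694 and 0.685). That bound was fixed beforehand and all 3 FL cultures lay under it, but its reading was set to open once the GM values were seen. With both on one scale, the FL slopes were 0.531, 0.606 and 0.864 (mean 0.67, SD 0.175) and the GM slopes 1.18, 0.894 and 0.867, which leaves it open too.

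One library of the 1 µM group (replicate 1) had 12.1% of its reads at low alignment quality, above the 9.15% of the highest GM DMSO library and the 8.22% and 8.55% of its group, as well as the high mitochondrial share. That this library alone makes the 1 µM calls is argued against, since 8832 genes were called without it and 8899 with it. No biological explanation for this library was tested, since the design gives none.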

How the results depend on the processing

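The alternatives that leave out culture 91, and the list tests without single libraries or with the block and an estimated correlation together, were chosen after seeing the data. Counts at 0.5 and 1 µM in GM cultures, for DMSO against t0 in GM cultures and for FL against GM stayed within 1.5 times of the main count under all alternatives run, with 7947 to 8832 at 1 µM and 5767 to 6107 for FL against GM when single libraries were left out. No called gene was called the opposite way under any alternative, except 66 of the calls of FL against GM when DMSO libraries replaced t0 libraries, where 4772 stayed called.

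At an adjusted p under 0.01, the counts were 1854 for the slope, 34 for 0.05 µM and 15 for DMSO against t0 in FL cultures, and 53 for the difference of responses, where the stricter threshold is the cause. With all 24 libraries in a model they were 3874 at 0.1 µM, 668 for the slope, 2721 for 0.05 µM and 5307 for DMSO against t0 in FL cultures. With the compared groups only they were 31, 582 and 17 for 0.05 µM, DMSO against t0 in FL cultures and the difference of responses, and with DESeq2 1526, 3503 and 646. With no filter the difference of responses had 187. With the block, the counts were 1098, 3107 and 738. Without culture 91 they were 2283 for 0.05 µM and 800 for the difference, and with a block too 3958 for 0.05 µM and 3640 for DMSO against t0. Leaving out single libraries gave 2009 to 3293 for the slope, 17 to 1983 for 0.05 µM, 13 to 1454 for DMSO against t0 in FL cultures and 93 to 591 for the difference. For these counts, apart from the threshold, the cause was not tested.

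Results that reversed were few. Cross-presentation genes in GM DMSO against t0 turned in fry's directional test (0.0152), and in the difference of responses the NF-kB list (0.03017) and the maturation list (0.5565) turned without the FL DMSO library of culture 91. With DMSO in place of t0 libraries, FL against GM turned for Diablo (-0.106), H2-Eb1 (-0.18), H2-Aa (-0.202), Insig1 (-0.472), Adm (-0.316), Egr3 (-1.013) and Cd34 (1.634); the cause was not tested. Of all 23357 values of named genes and lists under the alternatives, 20884 kept their side of the threshold, 1453 lost their call, 1010 gained one and 10 turned. A turn was counted only where the main result or the alternative was called. Changes of direction without a call are among the 20884. For named genes, leaving out single libraries kept 10488 of 11439, RLE scaling 1617 of 1638, no filter 1565 of 1638 and DESeq2 1503 of 1635. For lists, an estimated correlation lost 76 calls. The 261 list results compared include lists not called with the preset correlation, so 76 of 261 understates the share of calls lost. In FL cultures no list passed with an estimated correlation, for AZD5582 against DMSO or for DMSO against t0. In the difference of responses only cholesterol synthesis did. Some lists stayed called in GM cultures and for FL against GM.

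In the paired comparisons, the block changed no call among the results the text gives other than those given beside them. Over all comparisons it kept 1337 of 1456 values of named genes, with 113 calls gained and 6 lost. Where the numbers did not pass the pairing check, it moved no count over 1.5 times except that of the difference of responses (738). In GM DMSO against t0 it gave the monocyte list an adjusted p of 0.04606. At 1 µM against DMSO each of 6 libraries correlated best with its own number, as did 6 for DMSO against t0 in GM cultures. For 0.5 and 0.1 µM against DMSO 5 and 4 of 6 did. In counts simulated at the depth and spread of these libraries, 2-fold changes were recovered in 4% of genes for 0.05 µM in FL cultures and 66% for 1 µM in GM cultures. Whether depth or spread sets this was not tested.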

Other observations

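In FL cultures the mean log2(CPM + 1) of mast cell, basophil and eosinophil genes differed more between cultures than between treatments, at 2.94, 5.49 and 4.6 in the DMSO libraries of cultures 91, 94 and 95 and 2.67, 5.55 and 4.57 in the AZD5582 libraries. Cell cycle genes stood at 3.30, 5.28 and 4.73 in the DMSO libraries and 2.52, 4.76 and 3.68 in the AZD5582 libraries. Over 24 h in DMSO, FL and GM cultures shared 677 genes called up and 568 called down, where independent lists would share 220.4 and 167.4.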
